A study of Drosophila melanogaster with 2 samples.

How the data were processed

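Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed on whole Drosophila melanogaster embryos collected 0 to 24 h after egg laying. The flies carried a transgene for Bgb (Big brother) fused to enhanced green fluorescent protein (eGFP), per the labels. The labels differ on the antibody: their free text names one against GFP, and their antibody entry names Bgb, so which of these was used is not settled here. Bgb is the fly homolog of CBF-beta, the non-DNA-binding partner of Runt domain transcription factors. The labels give 2 samples, numbered as biological replicates 1 and 2 of 1 group. There was no second condition, and control libraries were not analysed here.

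The deposited files are peak lists on the dm6 genome build. For the series they are a conservative list that passed the irreproducible discovery rate (IDR) comparison of the replicates, a second IDR-thresholded list, and ranked lists without a threshold. Each replicate has its own thresholded and ranked list. The aligner, the peak caller and the scaling are not given in the sources used here. The signal value of each peak is the authors' own, as deposited, with no stated scaling between libraries. It was used to describe and rank peaks within a list, and signals of the 2 replicates were set side by side without rescaling. The authors also deposited a −log10 q value for each peak, which was not used for ranking because 57.9% of conservative peaks share the highest value of 3.74. The read depth of each library is unknown from these files, so the intervals given here cover the counting of peaks only. The ranked list of the series gives, beside each of its 101843 peaks, a position and signal from each of 2 replicate lists. Traced by position and signal, 80671 of the first set were found in the ranked list of replicate 1 and 73316 of the second in that of replicate 2, with 0 matches the other way round.

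The conservative list was the main list. Positions were compared with the Ensembl annotation of the same assembly, whose arm lengths no peak exceeded. A summit was counted as near a transcription start site (TSS) within 1000 bp. Annotation classes were assigned in the order promoter, 5' UTR, 3' UTR, coding exon, other exon, intron and intergenic. Location and overlap were set against 1000 random placements on the same arm, and a share was taken as past the threshold when it lay outside the range of all of them. A share per arm was set against the arm's share of sequence without unknown bases, by its binomial interval. A gene had a peak when a summit lay between 2 kb upstream of its start and its end. For each of 18 gene lists, the share was set against 10000 random lists matched on decile of window length. The two-sided permutation p was adjusted by the Benjamini-Hochberg method over the lists, and 6 members were matched through another name of the gene. For 14 consensus motifs, windows of 50 bp either side of the summit were compared with windows 500 bp to either side by a two-sided Fisher's exact test, adjusted over the motifs. All 2080 joined 6-mers were tested in the same way. The Runx consensus, RACCRCA, was the planned single test and is given with its unadjusted p. Shares have exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only. The ranked list also held 801 peaks off the chromosome arms, which were left out of tests of location and sequence.

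The gene lists, the motifs and the rule for the genes named were fixed before the data were examined. The rule takes Bgb, Bro and the Runt domain genes, the protein-coding gene nearest to each of the 20 strongest peaks, the 3 members of each list with the strongest peak, and the 5 genes with the most peaks, with ties kept. Neighbours are named beside them where the peak lay nearest to the neighbour's TSS.

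The tests were checked on simulated data. For lists of 15 and 90 genes without an effect, drawn from 13968 genes, 3% and 4.5% of 200 simulations passed 0.05. With 30 percentage points added, 64.5% of lists of 15 genes and 100% of lists of 90 genes were called. These calls used the unadjusted p of a single list. The results use p adjusted over 18 lists, which is stricter. The motif test called 4% of simulations without an effect and 100% with 3 percentage points added. Its simulated windows lay at random genome positions, so the rate at real summits, most of them at promoters, was not checked. The placement test called 2% of 100 simulations without an effect. Lists of few genes can therefore miss a difference of that size.

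Other settings chosen in advance covered the peak list, the stronger 50% of peaks, each replicate alone, overlap rules, TSS and gene windows, class order, backgrounds and motif windows. A further 4 were chosen after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.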

Results

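Binding of Bgb-eGFP was profiled in 2 biological replicates of whole embryos aged 0 to 24 h. The conservative list held 4488 peaks, which merged into 4291 regions covering 1371 kb of the dm6 genome. The second series list held 6393 peaks. Replicate 1 alone gave 6061 peaks and replicate 2 alone gave 3200. The median signal of the conservative peaks was 144 (interquartile range 95.3 to 261) and the highest was 1962, in the units of the authors' peak caller. Read depth is unknown, and no control library was analysed here.

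The first comparison asked how far the replicates gave the same regions. Most replicate 2 peaks recurred in replicate 1: 2901 of 3200 (90.7%) overlapped a replicate 1 peak by at least 1 bp, against a mean of 2.54% for random placements. In the other direction 3032 of 6061 replicate 1 peaks overlapped a replicate 2 peak and 3029 did not, against 1.38% overlapped in random placements. The highest share in 1000 placements was 3.44% and 1.85%, respectively. With the replicate 1 list shortened to its strongest 3200 peaks, the shares were 78.5% and 77.3%. At 4453 conservative peaks with a ranked peak in both replicates, the signal was higher in replicate 1 at 92.5%, with a median log2 ratio of 0.68 ± 0.50 (SD across peaks). Spearman's rho was 0.32 across all 101843 ranked peaks and 0.80 across the 4488 peaks of the conservative list. These are correlations across peaks, which are not independent replicates, and the second set was selected for agreement.

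The 20 strongest peaks of the conservative list all lay at promoters. The ranking holds within this list only, since ranked peaks past the IDR score but not in it reached a signal of 1302. The highest signal, 1962 (replicate 1 1161, replicate 2 806), was at the promoter of MESK2 on chromosome 2R, positions 21501764 to 21502210, with the summit 72 bp from its TSS. Next were Rpn6, a subunit of the proteasome lid, with 1890 (1157 and 732; 2R, 14752186 to 14752580), and Pym, a protein that acts on exon junction complexes, with 1811 (1114 and 693; 2R, 23856793 to 23857144). Creld (1686), Daxx (1641), Capr (1615), RpL32 (1607), a protein of the large ribosomal subunit, jagn (1582), CG2924 (1510) and STUB1 (1456) completed the first 10. Ranks 11 to 20 were Snx27, RhoGAP93B, CG15160, CG4502, CG11964, Ube3a, CG30015, Hsp110, bun and CG11779, with signals from 1431 down to 1274. All 20 summits lay in a promoter window, at most 152 bp from a protein-coding TSS, and the replicate 1 signal, at least 772, exceeded the replicate 2 signal, at least 424, at each. In number of conservative peaks, EcR, the ecdysone receptor gene, had 13, mam and Tlk 8 each, and HmgD, Mob2 and SNF4Agamma 7 each; the strongest peak in the window of Tlk was nearest to the TSS of Rala, and that of HmgD to the TSS of HmgZ. This order depended on the replicate. Without replicate 2, Tlk had 13, mam 12 and EcR 11. Without replicate 1, EcR had 8, SNF4Agamma 7, mam, Tlk and HmgD 4 each, and Mob2 2. The counts were not scaled by gene length, and long genes hold more peaks by chance.

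Peaks of the whole list were concentrated at transcription start sites. Of 4488 summits, 3966 (88.4%, 95% interval 87.4 to 89.3) lay within 1000 bp of a TSS, against a mean of 23.7% and a highest value of 25.7% in 1000 random placements. The median distance was 56 bp, and 3035 summits (67.6%) lay within 100 bp. Introns held 244 summits (5.44%, random mean 36.0%) and intergenic sequence 203 (4.52%, random mean 25.1%). Coding exons held 16 (0.357% against 9.96%), 3' UTRs 48 (1.07% against 4.22%) and 5' UTRs outside promoter windows 4 (0.0891% against 0.445%). The coding exon share was 0.656% without replicate 1 and 1.44% with the second series list, each still below all random placements. Weak ranked summits with an IDR above 5%, a background chosen after seeing the data, lay near a TSS in 29.6% of 94418 cases.

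By arm, 2R held 22.2% of the peaks (21.0 to 23.5) on 18.4% of the sequence, and chromosome 4 held 0.557% (0.361 to 0.821) on 0.971%. Arm 2L held 18.3% on 17.2% and 3R held 22.1% on 23.4%, each with an interval that narrowly excluded the share of sequence. 3L (19.7% on 20.4%) and X (765 peaks, on 17.1% of the sequence) had intervals that included their share of sequence. The difference of 2R held in all 5 alternatives and that of 3R in none, while 2L lost its difference in 3 of them (17.9% with the second series list, 17.6% with the stronger 50% of peaks and 18.1% without replicate 1). Chromosome 4 lost its difference in 2 (0.579% with the stronger 50% of peaks and 0.775% without replicate 2). Every background was sequence or arm length. Most summits lay near a TSS, but the number of TSSs per arm was not taken into account. The differences between arms are therefore not separated from gene density. Y held 0 peaks, which allows up to 0.0668% as 3 counts of 4488, or 0.0822% by the exact interval. A further 148 ranked peaks passed the IDR score without being in the list, 84 of them on 3R.

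Gene groups differed in how often their members held a peak. Of 13968 protein-coding genes, 5223 (37.4%) had a peak in their window. Ribosomal protein genes had one in 66 of 92 cases (71.7%), against 28.9% in length-matched random lists (adjusted permutation p = 0.0018). The strongest were at RpL32 (1607), RpS2 (1233) and in the window of RpS27 (988), the last nearest to the TSS of its neighbour Nup358. Proteasome genes had one in 26 of 48 cases (54.2% against 29.8%, adjusted permutation p = 0.0024), led by Rpn6 (1890), Prosalpha7 (1197) and Rpn10 (874). The proteasome call was lost with the second series list (54.2% against 36.6%, adjusted permutation p = 0.118), with the stronger 50% of peaks (33.3% against 18.9%, adjusted permutation p = 0.121), without replicate 2 (54.2% against 35.3%, adjusted permutation p = 0.0816) and in Fisher's exact test without length matching (adjusted p = 0.0859). In the first 3 of these the share stayed above the mean of the random lists, and in the last above the 37.4% of all genes. Chemosensory receptor genes, which act in smell and taste, had one in 10 of 179 cases (5.59% against 34.3%, adjusted permutation p = 0.0018). Their strongest peaks, at Or9a (691), Gr59e (294) and Gr97a (242), were nearest to TSSs of the neighbours Neb-cGP, AIMP3 and CG5521. Their share was 8.94% against 40.3% without replicate 2, 3.35% against 30.9% within 1 kb of the TSS and 1.68% against 22.7% with the nearest TSS. The raw p of the ribosomal and chemosensory lists, 0.0002, is the smallest that 10000 random lists can give.

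**Figure D1:**
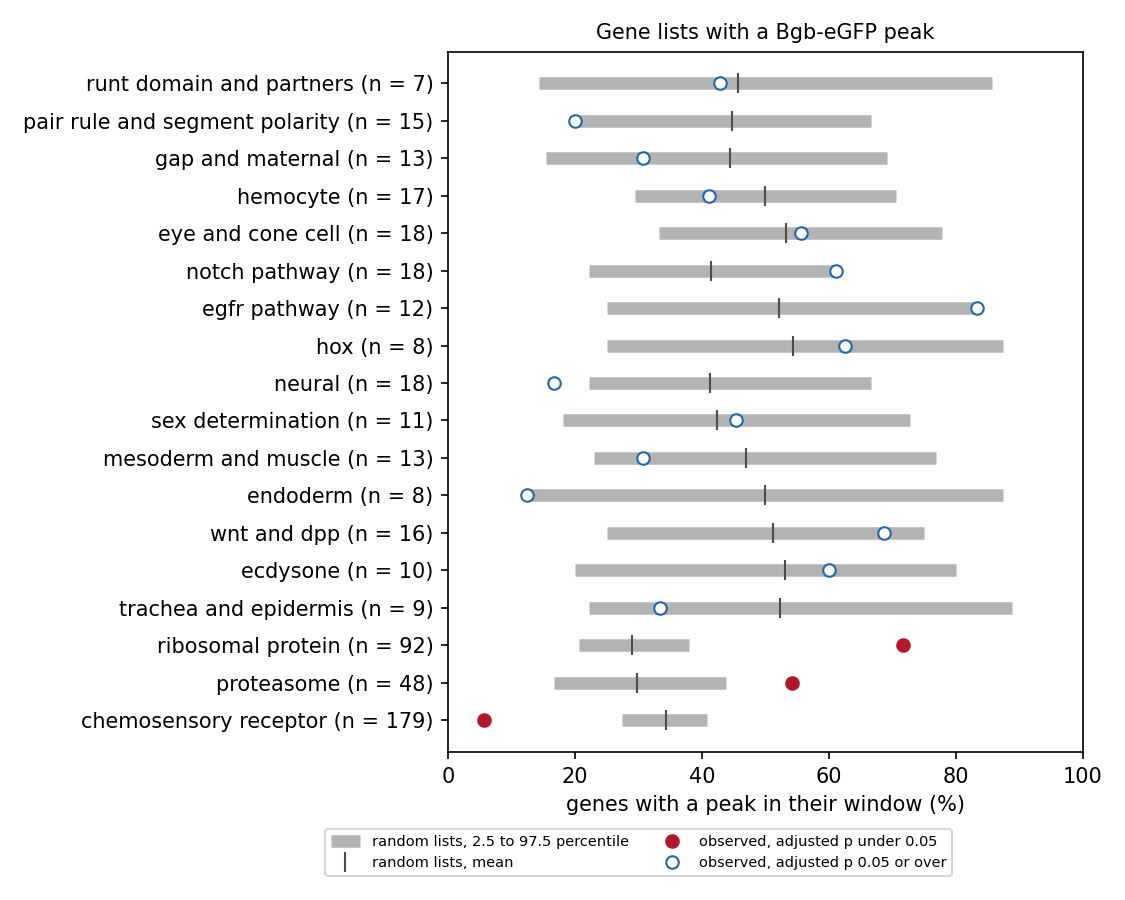
Share of genes with a Bgb-eGFP peak in their window, in percent, for each gene list of n genes (points), beside the mean (tick) and the central 95% range (bar) of 10000 length-matched random lists. Ribosomal protein genes (71.7%) and proteasome genes (54.2%) lie above their bars, and chemosensory receptor genes (5.59%) lie below, as do neural genes (16.7%), which did not pass after adjustment (open points).

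None of the other 15 lists passed the adjusted threshold. EGFR pathway genes had a peak in 10 of 12 cases (83.3% against 52.2%, adjusted permutation p = 0.187), with S at 939, vn at 207 and Egfr at 199. S (Star) shares this peak with the TSS of ast. Notch pathway genes had one in 11 of 18 cases (61.1% against 41.4%, adjusted permutation p = 0.281), including mam (486), Su(H) (465) and gro (380), which encodes the Groucho co-repressor. Wnt and Dpp genes had one in 11 of 16 cases (68.8% against 51.2%), led by pan (402), tkv (318) and nkd (220). Neural genes had one in 3 of 18 cases (16.7% against 41.3%, raw permutation p = 0.0484, adjusted 0.187), namely L (141), elav (108) and pros (82.0). Pair-rule and segment polarity genes had one in 3 of 15 cases (20% against 44.8%), at odd (194), hry (139) and en (82.7), and endoderm genes in 1 of 8 (12.5%, adjusted permutation p = 0.187), at GATAd (192). Gap and maternal genes had one in 4 of 13 cases (30.8% against 44.4%), including ems (129) and bcd (97.0), while the peak of 1274 in the window of nanos was nearest to CG11779. Hox genes had one in 5 of 8 cases (62.5% against 54.4%), with abd-A at 337, Ubx at 233 and Antp at 171, the latter pair in introns. Hemocyte genes had one in 7 of 17 cases (41.2% against 49.9%), with Pvr at 649, Pxn at 168, nearest to MEP-1, and Hml at 154. Eye and cone cell genes had one in 10 of 18 cases (55.6% against 53.2%), with svp at 463, ro at 283, nearest to T48, and eya at 171. Ecdysone genes had one in 6 of 10 cases (60% against 53.0%), led by ftz-f1 (631), EcR (377) and Eip74EF (295). Mesoderm and muscle genes had one in 4 of 13 cases (30.8% against 46.9%), with Mef2 at 409, tin at 318, nearest to mod(mdg4), and Tm1 at 176, nearest to MRG15. Sex determination genes had one in 5 of 11 cases (45.5% against 42.3%), with her at 448, gro at 380 and emc at 155. Trachea and epidermis genes had one in 3 of 9 cases (33.3% against 52.3%), with bnl at 283, grh at 199 and Ddc at 86.9. The bnl peak lay inside bnl, 19241 bp from the nearest protein-coding TSS, that of Acsx4. With the nearest TSS in place of the window, the EGFR list passed (adjusted permutation p = 0.0288), as it did in Fisher's exact test without length matching (0.0092). Hox genes stood below random with the nearest TSS (37.5% against 43.7%) and within 1 kb of the TSS (12.5% against 45.8%). Leaving out a replicate moved many of these lists, none of them past the adjusted threshold. Without replicate 1, EGFR genes stood at 50% against 40.1%, Notch at 38.9% against 31.8%, Wnt and Dpp at 43.8% against 39.0%, neural at 5.56% against 32.0% and gap and maternal at 15.4% against 35.1%, while eye and cone cell (22.2% against 40.9%) and mesoderm and muscle (38.5% against 36.1%) turned direction. Without replicate 2, neural genes stood at 27.8% against 48.5% and sex determination at 72.7% against 49.4%, while pair-rule and segment polarity (53.3% against 52.0%), gap and maternal (69.2% against 52.5%), endoderm (62.5% against 58.2%) and trachea and epidermis (77.8% against 61.3%) turned to above random. In the list of replicate 2 alone, hry, ems, eya, Ubx, elav and pros had 0 peaks.

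The genes for Bgb and its partners were examined whatever their values. Bgb, on chromosome 3L from 1639711 to 1640952, had 2 peaks, the stronger with a signal of 327 (175 and 148 in the replicates) at its promoter. Bro, the neighbouring paralog from 1647869 to 1648612 on 3L, had 1 peak of 136, nearest to the TSS of CG17249. The flies carried a tagged transgene of Bgb, so signal at the Bgb locus can arise without binding there. Whether the transgene extends to Bro is not known here. Both genes count toward the list share below. The 4 Runt domain genes, run, lz, RunxA and RunxB, all on X, had 0 conservative peaks. Their strongest ranked signals were 51.4, 82.2, 43.4 and 67.9. The list of replicate 1 alone had 1 peak each in the windows of run, lz and RunxB, and the second series list 1 each in those of lz and RunxB. With 3 of 7 members holding a peak, the list of these genes and gro stood at 42.9% against 45.7% (adjusted permutation p = 1), and turned to above random with either replicate left out (42.9% against 35.0% without replicate 1, 85.7% against 53.5% without replicate 2). Around Bgb, 136 ranked peaks lay within 50 kb, at percentile 81.4 of the same count around protein-coding genes (median 107). The percentile was 87.6 in replicate 1 and 89.4 in replicate 2.

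Sequences containing CGATA marked the summits. The consensus CGATAR, known as a binding sequence of the insulator protein BEAF-32, occurred in 1708 of 4488 summit windows (38.1%, 36.6 to 39.5) and in 6.87% of flanking windows. At promoter summits, a split chosen after seeing the data, CGATAR stood at 41.3% against 6.91%. Its reversed sequence RATAGC also passed there (15.9% against 6.86%, Fisher's exact adjusted p = 1.56e-51). A stretch of CGATAGC matches both sequences. The overlapping consensus TATCGATA, bound by the replication-related factor DREF, occurred in 15.2% against 0.535% (Fisher's exact adjusted p = 4.59e-274). GGTCACAC, the sequence of M1BP, occurred in 4.32% against 0.468% (Fisher's exact adjusted p = 4.04e-54). Of the 20 strongest peaks, 16 held CGATAR, among them MESK2, Pym and RpL32. The E-box CATATG was less frequent at summits than in flanks (1.69% against 3.01%, Fisher's exact adjusted p = 1.19e-05), as were the GATA consensus (3.97% against 4.96%, 0.0238) and the ETS consensus (1.09% against 1.74%, 0.00989). The GATA difference was lost without replicate 1 (3.94%) and with the stronger 50% of peaks, and turned against GC-matched windows (3.61%). The ETS difference was lost with the second series list (1.60%) and turned without replicate 2 (1.58%). The consensus sequences of Zelda, GAGA factor, Su(H), Grainyhead, Caudal, AP-1 and Hox with Exd did not pass, at shares from 0.267% to 2.30%. GAGA passed above background in 4 of 6 alternatives, namely the second series list (3.10% against 1.82%), without replicate 2 (3.51% against 1.76%, Fisher's exact adjusted p = 3.1e-12), the 100 bp half-window (Fisher's exact adjusted p = 2.91e-09) and GC-matched windows (2.01% against 1.11%), but stood below flanks without replicate 1 (1.12% against 1.66%) and with the stronger 50% of peaks (1.20% against 1.65%). Below background, Zelda passed without replicate 1 (2.03% against 2.98%) and with the 100 bp half-window (4.10% against 5.11%), Caudal with the second series list (0.939% against 1.36%) and against GC-matched windows (0.802% against 2.45%), and Hox with Exd with the second series list (0.501% against 0.892%). Of 2080 6-mers, 441 were more frequent at summits and 612 less frequent at an adjusted p under 0.05, led by ATCGAT (30.6%), CGATAG (28.0%) and TATCGA (34.5%). Peaks with CGATAR had a median signal of 238, against 116 for peaks without it.

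**Figure D2:**
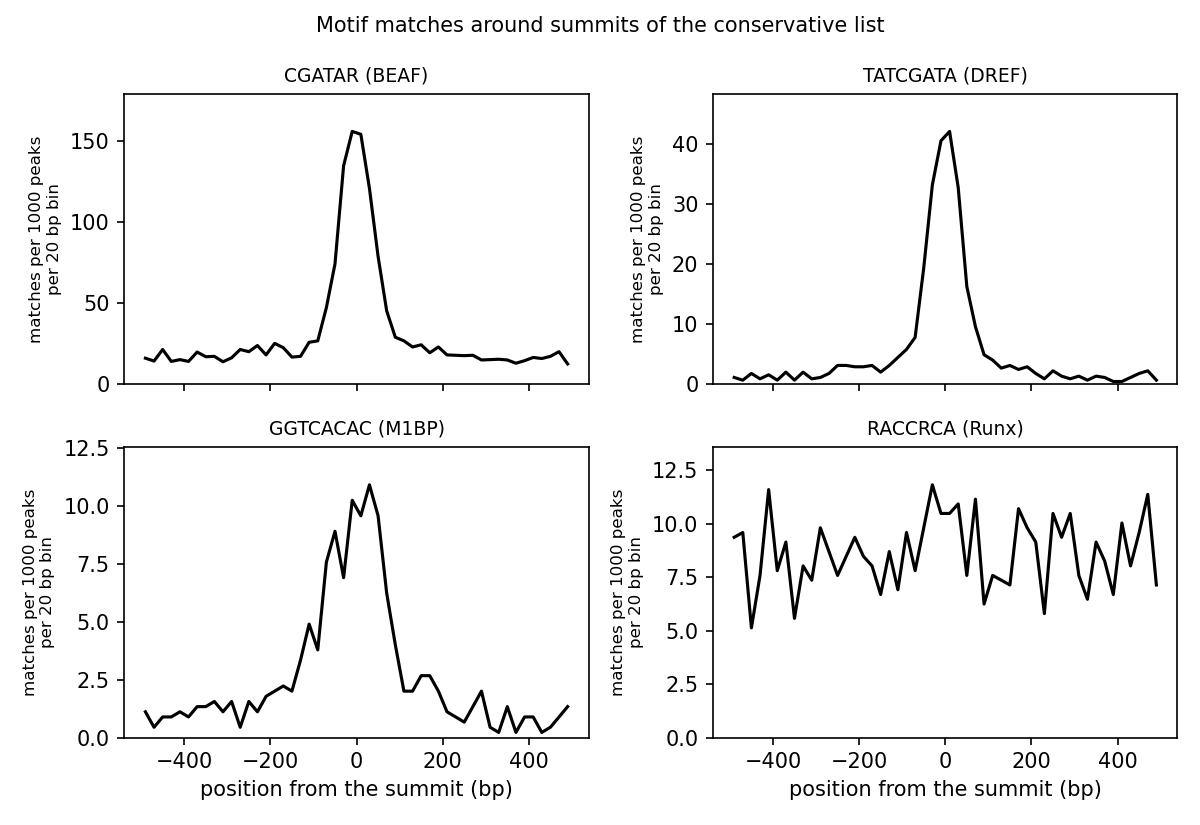
Matches per 1000 peaks in bins of 20 bp (y axis) by position from the summit in bp (x axis), for 4 consensus sequences over 4488 conservative peaks. CGATAR and TATCGATA peak at the summit. GGTCACAC is raised around it, with its highest bin at 20 to 40 bp (10.9 matches), while RACCRCA lies between 5.12 and 11.8 matches across the window.

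The Runx consensus, the binding sequence of the Runt domain partners of Bgb, did not pass its planned test. RACCRCA occurred in 212 summit windows (4.72%, 4.12 to 5.39) and in 3.99% of flanking windows (two-sided Fisher's exact p = 0.0508). The reversed sequence occurred in 4.70% of the same summit windows, and GC-matched genome windows held the consensus in 4.61% (Fisher's exact p = 0.841). The excess over flanks did pass with the second series list (4.82%, p = 0.00796), in replicate 1 alone (4.88%, p = 0.003), in replicate 2 alone (4.81%, p = 0.0264) and for the shorter core ACCRCA (8.73% against 7.74%, p = 0.0478), by the same exact test. The excess did not pass with the stronger 50% of peaks (4.46% against 4.10%, Fisher's exact p = 0.520). Nor did it with the 100 bp half-window (8.96% against 8.07%, Fisher's exact p = 0.0801). The odds ratio over flanks was 0.845 in ranks 1 to 500, 0.956 in ranks 501 to 1000 and 1.34 in ranks 1001 to 2000, none passing. These p values are unadjusted, and the lists are not independent, since 4234 conservative peaks are also in the second series list. Of the 20 strongest peaks, 1, at CG11964, held the consensus, and Mef2 and grh were among other named genes with it.

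**Figure D3:**
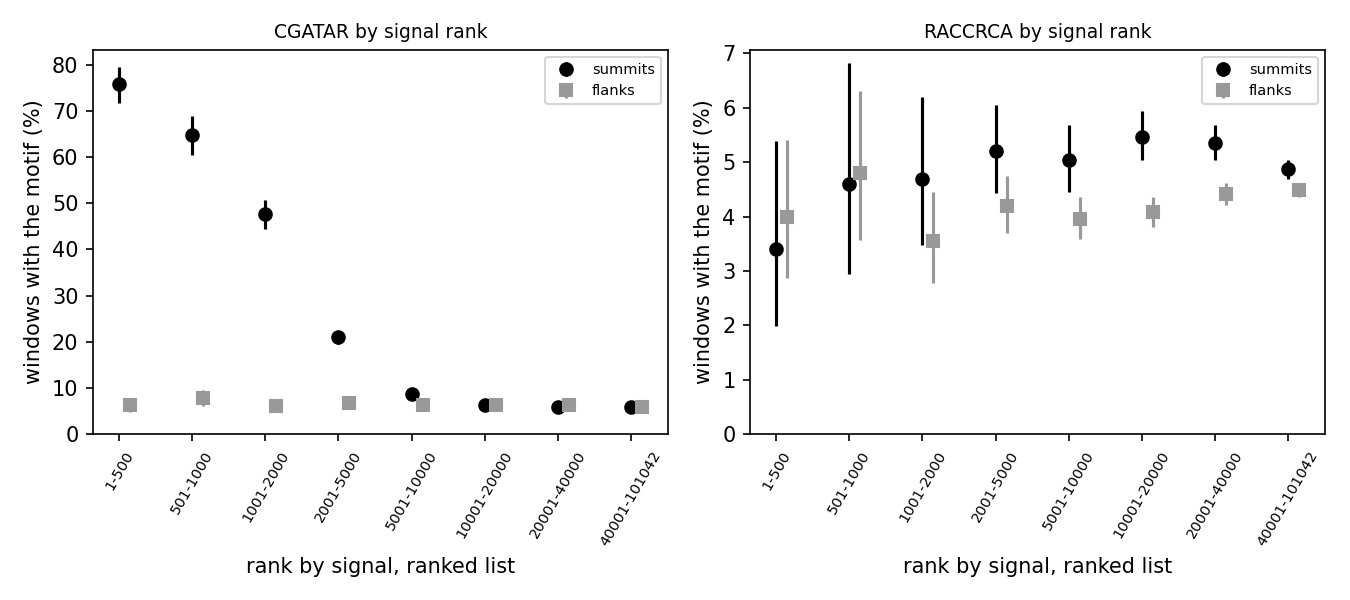
Percentage of windows with CGATAR (left) and RACCRCA (right) at summits (circles) and in flanks (squares), with exact 95% binomial intervals, by rank of signal in the ranked list, in bins chosen after seeing the data. CGATAR falls from 75.8% in ranks 1 to 500 to 5.76% beyond rank 40000, while RACCRCA lies between 3.4% and 5.47% at summits.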

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

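The GC-matched windows, the consensus share, the shorter core and the Bgb locus count were measurements chosen in advance, but their use as tests of the explanations below, like the tests of tRNA genes, of variants of the core and of the absent peaks, was chosen after the results were seen; that of promoter position was chosen before its result was seen.

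The conservative list lacked 148 ranked peaks whose IDR score passed the threshold that the listed peaks pass, a signal in data that the comparisons did not use. Of these, 84 (56.8%) lay on 3R, against 22.1% of the listed peaks, 76 neighbouring pairs were both absent where random draws gave at most 13, and the other 3 lists lacked 2.94% to 3.33% of theirs. Lower signal is argued against, since their median signal was 151 and that of the listed peaks 144. Only 5 of the 148 (3.38%) overlapped a peak of any of the other 3 thresholded lists, which is consistent with the removal of fixed stretches of the genome. What such stretches have in common was not tested, no biological explanation was tested, and binding there is missing from the shares above.

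CGATA sequences marked the summits in 41.3% of promoter peaks, against 28.7% on average and at most 30.2% when summit offsets were permuted among these promoters, so position relative to the TSS of these promoters alone gives less than was observed. Moved windows can still cover the original summit, and promoters without peaks were not measured, so how much of the share comes with promoters in general stays open. Base composition is argued against, since 6.02% of GC-matched windows held the sequence. Enrichment at active promoters without the tagged protein cannot be told apart from binding, because control libraries were not analysed here; summits also lay at 53.4% of tRNA genes. No biological explanation was tested.

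The Runx consensus was close to its background over all summits, at 4.72% against 3.99% in flanks, and above flanks at promoter summits (4.97% against 3.86%). The reversed sequence occurred in 4.84% of the same promoter summits and in 4.36% of their flanks. At promoter summits the consensus was not compared with GC-matched windows. Binding at this consensus at most peaks is argued against by the upper bound of its share, 5.39%. The shorter core, without the first base of the consensus, was also close to flanks, with an odds ratio of 1.14. It was matched exactly, so looser forms of the site were not tested. Whether the consensus is too strict therefore stays open. Of the core's variants, ACCGCA exceeded flanks (odds ratio 1.40, Fisher's exact adjusted p = 0.00142) and ACCACA did not (0.950). Of all 2080 sequences of this length, 441 exceeded flanks and 612 lay below them, so the pass of ACCGCA does not by itself mark a Runx site. A mislabelled sample or another tagged protein cannot be told apart from these data. The Bgb locus stood at percentile 81.4 of ranked peak counts within 50 kb and at 95.7 per base within 20 kb. An extra tagged copy need not raise these values.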

How the results depend on the processing

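The alternatives named as sub-threshold summits, peaks per base and Pearson correlation over the conservative peaks were chosen after seeing the data. The share of summits near a TSS stayed above its background in all 8 alternatives, both replicate overlaps above random in all 4, ribosomal protein genes above and chemosensory receptor genes below random in all 8, and CGATAR, TATCGATA and GGTCACAC above background in all 6. The cause of the following changes was not tested, except that shorter lists hold fewer peaks. With the second series list, arm 2L held 17.9%, 3L 20.7% (turned above its sequence share) and 3R 22.4%, none past the interval; 1 list instead of 2 lay above random, proteasome stood at 54.2% against a random mean of 36.6%, and lists that had not passed turned direction (Runt domain 71.4%, gap and maternal 61.5%, trachea 66.7%). The Runx share was then 4.82% and the Bgb locus percentile 94.5. With the stronger 50% of peaks there were 2244 peaks, with 2L at 17.6%, 3L at 18.4% (now past the interval), 3R at 23.7% and X at 17.9% (turned), chromosome 4 at 0.579% and other exons at 0.0891%. In that setting 1 list lay above random, proteasome stood at 33.3% against a random mean of 18.9%, Runt domain stood at 28.6% and eye and cone cell at 22.2%, GAGA at 1.20%, Su(H) at 0.713%, Grainyhead at 0.0891% and Hox-Exd at 0.624% turned, and the Bgb percentile was 51.4. Full arm length left 3R at 22.1%, within its interval. Other gene windows turned lists that had not passed: TSS plus and minus 1 kb gave Runt domain 42.9%, eye and cone cell 38.9% and Hox 12.5%, and the nearest TSS gave Hox 37.5%. Without length matching, Runt domain (42.9%) and hemocyte (41.2%) turned, and the proteasome call was lost with the share still above background (54.2% against 37.4%). Without shared genes, Runt domain and eye and cone cell stood at 50% each and turned. EGFR genes (83.3%) passed with the nearest TSS and without length matching. Of the motifs that had not passed, GAGA newly passed above background in 4 alternatives, and below background Zelda and Caudal newly passed in 2 each and Hox-Exd in 1. GATA (3.97%) turned against GC-matched windows, Runx passed with the shorter core (8.73%), and its share of 4.72% lay below the 5.06% of sub-threshold summits. The replicate correlation was 0.80 over the conservative peaks, 0.47 as Pearson's r of log2 signal and 0.86 with both changes. The Bgb percentile was 84.8 with 20 kb, 85.7 in the long ranked list and 87.2 per base. Per base with 20 kb it was 95.7. For the median signal of the ranked peaks it was 65.5 with 50 kb and 80.0 with 20 kb. Leaving out each replicate gave ranges of 18.1% to 18.4% for 2L, 22.3% to 22.9% for 3R, 0.594% to 0.775% for chromosome 4, 16.4% to 17.3% for X, 0.125% to 0.165% for other exons, 1 to 2 lists above random, 45.8% to 54.2% for proteasome, 4.81% to 4.88% for Runx and 87.6 to 89.4 for the Bgb percentile. For lists that had not passed, the ranges were 42.9% to 85.7% (Runt domain), 13.3% to 53.3% (pair-rule), 15.4% to 69.2% (gap), 22.2% to 77.8% (eye), 38.5% to 46.2% (mesoderm), 12.5% to 62.5% (endoderm), 33.3% to 77.8% (trachea), 50% to 91.7% (EGFR), 38.9% to 66.7% (Notch), 43.8% to 81.2% (Wnt and Dpp), 5.56% to 27.8% (neural) and 45.5% to 72.7% (sex determination). For motifs they were 1.12% to 3.51% (GAGA), 0.875% to 0.94% (Su(H)), 1.06% to 1.58% (ETS) and 0.825% to 0.906% (AP1). Unknown read depth limits any statement on the peaks that only one replicate holds. No paired analysis was possible because there is only 1 group.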

Other observations

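The tests in this part were chosen after the results were seen. Genes outside the protein-coding set also held summits. Of 290 tRNA genes, 155 (53.4%, 47.5 to 59.3) had a summit within 200 bp of the TSS, against a mean of 4.14 and at most 15 in 1000 random placements. The 139 peaks at tRNA genes had a median signal of 198, against 150 at coding promoters, but held CGATAR in 7.91% against 43.2%. Of 269 snoRNA genes, 18 had a summit (random maximum 13), as did 6 of 32 snRNA genes (random maximum 4). Of 99 rRNA genes, 0 did, where random placements gave a mean of 1.54 and at most 7. So few were expected that an absence cannot be told from random placement. Random placement did not keep the concentration of summits at promoters. Summits of neighbouring coding promoters can therefore count for snoRNA and snRNA genes, and how many did was not measured.

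The 522 summits more than 1000 bp from a TSS were enriched over their flanks in CATGTA (14.9% against 3.16%, Fisher's exact adjusted p = 3.4e-13) and TCTACA (17.6% against 4.69%). Of the sequences enriched at promoter summits, CGATAR (13.6% against 6.61%) and TATCGATA (3.26% against 0.287%, Fisher's exact adjusted p = 1.47e-05) were also enriched there, and GGTCACAC was not (0.575% against 0.479%, Fisher's exact p = 1). Distal and promoter summits were not tested against each other. The Runx consensus stood at 2.87% against 4.98% at distal summits (Fisher's exact p = 0.0629).

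At the 3966 promoter summits the Runx consensus exceeded flanks (4.97% against 3.86%, Fisher's exact adjusted p = 0.00606), and its reversed sequence did not pass (4.84% against 4.36%, Fisher's exact adjusted p = 0.242). The core variant ACCGCA was also above flanks at promoters (4.79% against 3.19%, Fisher's exact adjusted p = 9.38e-05). The other variant, ACCACA, did not pass there (4.51% against 4.63%). At promoters 405 of 2080 sequences of this length exceeded flanks, so the pass of ACCGCA is not specific to the Runx core. By rank of signal, RACCRCA passed against flanks in each of the 4 bins beyond rank 5000, and the reversed sequence passed in the same bins. The odds ratio of RACCRCA was above that of the reversed sequence in ranks 10001 to 20000 (1.36 and 1.19). It was below it in ranks 5001 to 10000 (1.29 and 1.40), 20001 to 40000 (1.23 and 1.28) and beyond 40000 (1.09 and 1.13). In ranks 2001 to 5000 the reversed sequence passed (Fisher's exact adjusted p = 0.028) and RACCRCA did not (0.0539). The difference between these sequences was not tested.

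Replicate 1 peaks without a replicate 2 peak (3029) had a median signal of 53.9, held CGATAR in 14.6% and lay near a TSS in 81.1%, against 125, 47.7% and 91.0% for the 3032 that overlapped one.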
